A study of Mus musculus with 8 samples.

How the data were processed

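Liver total RNA in 8 samples from male FVB/N mice aged 3 months was measured on single-colour Applied Biosystems arrays, per the labels, after oligo(dT)-primed reverse transcription with a digoxigenin label read by chemiluminescence. The samples formed 4 groups of 2 arrays: wild type (WT), untreated Abcb4 knockout (KO), and KO mice given the bile acid norUDCA for 3 days or for 4 weeks. Groups and treatment lengths were taken from the labels. The names of the deposited files of the 4-week group carry a length of 14 days instead, and this disagreement was not settled here. Each sample was numbered 1 or 2 within its group by its title. Nothing beyond these titles says that replicates were separate animals, so p-values measure the spread between these samples, which may in part be technical. The files give no slide or scan date, and no batch was modelled.

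Each scanner file lists, per the file headers, a signal, an assay-normalized signal, the spot noise, the signal over noise and quality flags. The signal is an intensity on a linear scale that was deposited with background already removed, as blank spots had a median of 0 on each array. Of 264096 gene spots over all arrays, 107688 were listed at exactly their own noise, so the deposited intensity of such a spot is its noise. Signal over noise is a score with no fixed range, used as deposited. The deposited table of the whole series holds an intensity per probe that equalled the assay-normalized signal within 0.06 for 100% of values, on a linear scale, with no centring and no further scaling between arrays. Its medians over gene probes ran from 1.07 to 1.60 across arrays. The assay-normalized signal was the signal divided by a factor of the array that differed between rows up to 119 and rows from 121. On WT replicate 1 these factors were 83.3 and 63.7. The image analysis software and its version are not given in the sources used here.

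From these values, the signal of 33012 gene probes was used and control spots were left out. The 4153 probes with a flag of 5000 or more on any array were left out, of which 353 would have passed the filter on dim probes. The other 28859 probes were put on a log2 scale and quantile-normalized between arrays. No offset was added, and no signal was at or below 0. Tested were the 16728 probes with signal over noise of 3 or more on at least 2 of the 8 arrays. A probe with signal over noise under 3 is called not detected on that array. Where no array of a group detected a probe, only a bound is given for the fold: the bright group's mean was set against the dim group's mean of, per array, the higher of the probe's own signal and the lowest detected signal. That lowest detected signal is the lowest of any probe on the array, so it often lies below the probe's own signal. For mCG18592.1, Fgf21 and Hsd3b4 the bound equals the plain ratio of the group means. The bound ("at least") is therefore nominal: it does not allow for the noise of the undetected spots, and the true fold may be smaller. Nor does it allow for the spread between arrays. Single arrays of the groups can therefore lie closer than the bound. No fold is given where only 1 array of the brighter group detected the probe, since its mean is then not a measured level. The detected share of gene probes per array, given with the results, takes the place of depth, and the number of arrays limits the precision.

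Differences were tested with limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3, with all 8 arrays sharing an estimate of the spread over 4 residual degrees of freedom and 1.96 prior degrees of freedom. P-values are two-sided and were adjusted by Benjamini-Hochberg over the tested probes within each comparison, with a threshold of 0.05. SE values are the moderated standard errors of the fit. A moderated F test compared all 4 groups. On data simulated for KO minus WT with 200 of 16728 probes changed, the fit recovered 1.4% of probes changed 2-fold, 47.6% of those changed 4-fold, 77.0% of those changed 8-fold and 88.0% of those changed 16-fold. Among its calls, 5.5% were false. The simulated noise was independent between probes and had the same spread in all 4 groups, whereas the real WT replicates correlated less than those of the other groups. The simulated shares therefore need not hold for calls on the real arrays.

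Probes carry gene identifiers of the array's design: 27930 have a Celera identifier, 4565 a GenBank accession and 517 a RefSeq accession. Names were taken from a RefSeq gene table of assembly GRCm38.p6, matched without version numbers, and no coordinate of it was used. This named 317 probes of 311 genes, 311 of these probes through a RefSeq accession and 6 through a synonym, while 206 RefSeq accessions and the Celera identifiers had no match. Of the tested probes, 163 (161 genes) had a name. The other tested probes are counted but not named. Of 858 genes in 30 lists fixed before the data were examined, 10 had a named probe, at most 2 in any list. The planned camera and fry set tests were left out, since no list reached 3 members, taken after the data were seen as the fewest for such a test. The value of each tested member is used instead, adjusted over all probes and over its own list alone, which for a list with 1 tested member leaves the p unadjusted.

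The rule for named genes was also fixed before the data were examined. It took Abcb4, then for each of the 3 main comparisons the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap (5 and 5 for the other comparisons). It added up to 4 members of each list with the smallest p and a fixed set of bile acid, lipid, fibrosis and inflammation genes. None of that fixed set had a named probe, and Abcb4 was not analysed here for the same reason. The highest mean signal chose the probe of a gene with several. For the 3 main comparisons, genes that passed only when p-values were adjusted over the named probes alone are also given. For the other comparisons and the F test, only the number of named probes passing in this way is given. That family was chosen after the data were seen, and the identifiers, not the values, set its members.

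Fold changes of comparisons that share the KO arrays were correlated across probes and set beside 100 simulations with no effect on the same design. Alternatives covered the normalization, the value source, the filter on dim probes, flagged spots, an offset, the variance prior, array weights, the samples in the fit, a replicate block, each array left out in turn, and the threshold. Alternatives chosen after seeing the data were the named-probe family, quantile normalization separately in the upper and lower rows, the unrounded row factors, and a split of the KO arrays between differences that share them.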

Results

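The arrays compared the liver transcriptome of WT mice, of mice lacking Abcb4 (the canalicular transporter that carries phospholipid into bile) and of knockout mice given norUDCA, a side-chain modified bile acid, for 3 days or 4 weeks. Each of the 4 groups had 2 arrays. Gene probes with signal over noise of 3 or more made up 33.3% and 41.4% of all gene probes on the WT arrays, 47.4% and 40.9% on the untreated KO arrays, 47.9% and 42.6% after 3 days, and 46.4% and 47.1% after 4 weeks. Across the tested probes, the Pearson correlation of log2 signal between the replicates was 0.935 in WT, 0.963 in KO, 0.968 after 3 days and 0.976 after 4 weeks. The first principal component held 37.6% of the variance and set the WT arrays (-105.3 and -57.8) apart from the other 6 arrays (-4.5 to 44.7). Both WT arrays also had dimmer positive control spots. In comparisons with WT, part of a difference may come from how these arrays were run, which cannot be told apart from genotype here. Abcb4 itself was not analysed here, because none of the named probes stands for it, so the genotype labels were not checked against the targeted gene.

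**Figure D1:**
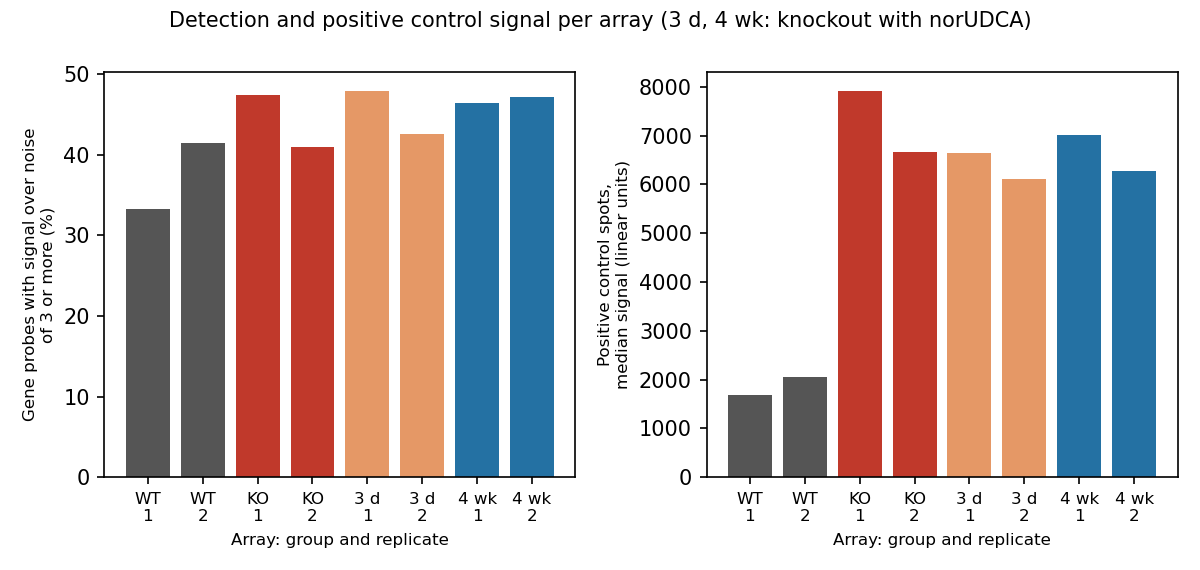
The left panel shows the percentage of gene probes with signal over noise of 3 or more on each of the 8 arrays, and the right panel the median signal of the positive control spots in linear units, with bars coloured by group. WT replicate 1 had the lowest detected share (33.3%), and the positive control spots of the WT arrays (1691 and 2062) lay below those of the other 6 arrays (6104 to 7913).

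The first question was how the liver of untreated knockouts differed from wild type. Krt23, a keratin on the fixed list of cholangiocyte markers, rose in the KO: its log2 signal was 6.38 ± 0.40 (SD, n = 2) in WT, where no array detected it, and 10.77 ± 0.34 (SD, n = 2) in KO, at least 20.6-fold higher (adjusted p = 0.035, limma). Dio1, the liver deiodinase that converts thyroxine to its active form, fell by 2.14 ± 0.29 on the log2 scale (SE, 4.42-fold, adjusted p = 0.039, limma). Both KO arrays lay on the same side of both WT arrays for each gene. The direction held in each alternative, but the call was lost in 10 of 21 for Krt23 (adjusted p up to 0.19) and in 13 of 22 for Dio1 (up to 0.22). No other named gene passed over all tested probes. Among probes without a name, the largest rises were those with the design identifiers mCG18592.1 (at least 180-fold, adjusted p = 0.003) and AK028310.1 (at least 78.6-fold, adjusted p = 0.00099), and the largest falls were those of mCG51120.2 (-6.59 ± 0.61 log2, SE, adjusted p = 0.020) and mCG14666.2 (-5.46 ± 0.63, adjusted p = 0.032).

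With p-values adjusted over the 163 named probes alone, a family chosen after the data were seen, 10 named probes of 9 genes passed in this comparison, 4 upward and 6 downward. The metabolic hormone Fgf21 was detected on both WT arrays (12.58 and 9.98 log2) and on neither KO array (5.96 and 6.45), with a mean at least 33.5-fold lower in KO (0.034 in this family, 0.073 over all probes). Wfdc2, a secreted protein of epithelia, was detected on both KO arrays and on neither WT array and was at least 6.91-fold higher (0.031 and 0.054). Cebpb, a transcription factor of hepatocytes and the acute phase, differed by -1.32 ± 0.27 log2 (SE) at its brighter probe (0.046 and 0.082), and its other probe gave a like value of -1.39. H2-Q8, a class I histocompatibility gene whose close paralogs this probe may also measure, differed by 1.69 ± 0.31 (0.032 and 0.068). The Golgi adaptor Gga1 differed by -1.22 ± 0.22 (0.032 and 0.066). The remaining probes of this family were those of Fmr1nb (7.71 and 8.51 log2 in KO against 5.26 and 4.47 in WT) and 4930433I11Rik (6.67 and 6.90 in KO against 8.47 and 7.94 in WT). Each was detected on 1 array of its brighter group and on none of the other, so no fold is given.

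Of the fixed lists, 9 had a tested member. In KO minus WT, Krt23 was the only list member past the threshold over all probes. Adjusted over the list alone, 4 of the 10 members passed: Krt23 (0.00021), Fgf21 of the fatty acid oxidation list (0.0038), the lymphoid chemokine Ccl21a of the inflammation list (higher in KO, detected on 1 of the 2 WT arrays, 0.010) and the sulfotransferase Sult5a1 of the conjugation list (-1.51 ± 0.56 log2, 0.037). For Fgf21 the list had 2 members. For the others it had 1, so their values are the unadjusted p, which was under 0.05 for 19.8% of all tested probes. Ccl21a has near-identical copies that the probe cannot be assumed to tell apart. Pemt, which makes phosphatidylcholine by methylation and is on the phospholipid list, gave 0.42 ± 0.19 and did not pass (unadjusted p = 0.069, as the only tested member).

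Over all 16728 tested probes, 189 changed between KO and WT by limma, 136 upward (72.0%, exact 95% interval 65.0 to 78.2) and 53 downward. The interval counts probes of the same arrays as independent draws, so it leaves out the spread between arrays and is too narrow. Of the 136 rises, 91 were of probes detected on neither WT array, and of the 53 falls, 14 were of probes detected on neither KO array. The filter on dim probes is uneven here. A probe undetected in WT can pass it on any 2 knockout arrays, treated or not, while a probe detected only in WT needs both WT arrays. With arrays scaled only to the same median, which moved the median log2 difference of all tested probes from 0.09 to 0.48, 251 rose and 52 fell, with cyclic loess 40 rose and 22 fell, and over probes detected on all 8 arrays 319 rose and 344 fell. Leaving out WT replicate 2 gave 1084 changed probes and leaving out either KO array gave 1.

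**Figure D2:**
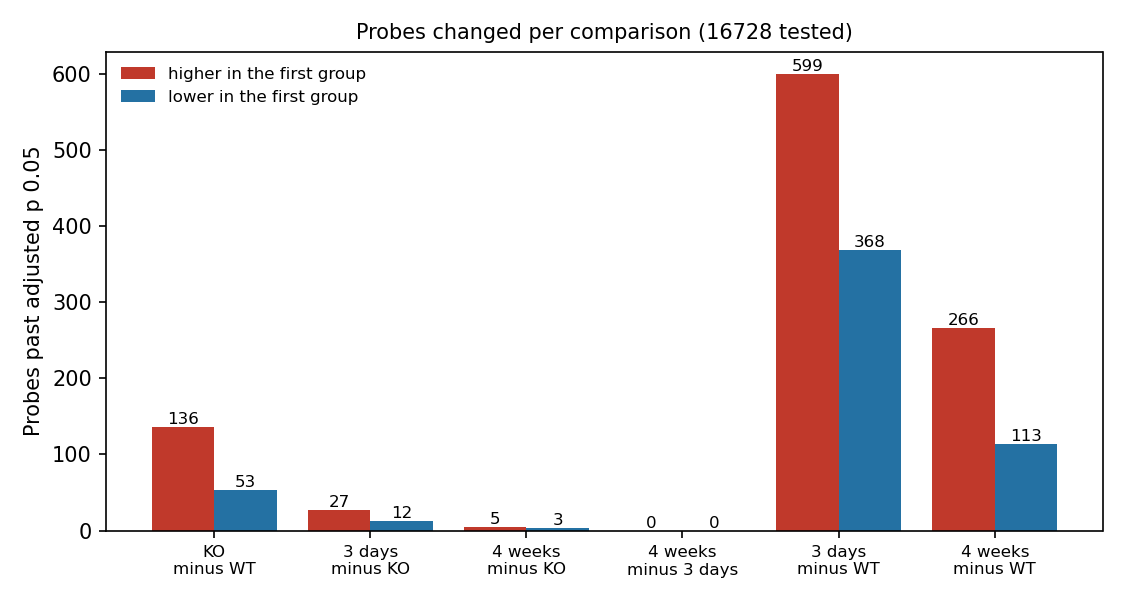
Bars give the number of probes past an adjusted p of 0.05 by limma in each of the 6 comparisons, red for probes higher in the group named first and blue for probes lower in it, out of 16728 tested. The comparisons of norUDCA-treated knockouts with WT gave the most calls (599 and 368 after 3 days, 266 and 113 after 4 weeks), and 4 weeks minus 3 days gave 0.

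The comparison of 3 days of norUDCA with untreated KO asked for the early response to the drug. No named gene passed over all tested probes. Adjusted over the named probes alone, 6 probes of 5 genes passed. Pdxp, a phosphatase of pyridoxal phosphate, was detected on both 3-day arrays and on neither KO array and was at least 4.59-fold higher (0.022 in this family, 0.061 over all probes). Tcte3, a dynein light chain gene, was at least 3.53-fold higher with the same pattern of detection (0.022 and 0.066). Dio1 differed by -2.49 ± 0.29 log2 (SE, 5.61-fold lower; 0.021 and 0.053), in the direction it took in the KO. Cebpb differed by 1.45 ± 0.27 (0.047 and 0.10), so that its mean after 3 days was 0.14 above that of WT, and Gga1 by 1.21 ± 0.22 (0.047 and 0.097), with a mean 0.01 below that of WT.

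Among the 10 list members, G6pc, the liver phosphatase that releases free glucose, gave -1.12 ± 0.36 (unadjusted p = 0.021, as the only tested member of its list, and 0.23 adjusted over all probes). Of all tested probes, 16.1% had an unadjusted p under 0.05. Aldh3a2, a fatty aldehyde dehydrogenase on the fatty acid oxidation list with 2 tested members, gave 0.62 ± 0.20 (0.040 adjusted over the list alone, 0.23 over all probes). Krt23, alone on its list, gave -1.32 ± 0.55 and did not pass (unadjusted p = 0.052). The other 7 members did not pass either. In all, 39 probes changed after 3 days, 27 upward and 12 downward. From the deposited assay-normalized intensities the count was 3, all upward, and it was 0 without either KO array, without either array of the 3-day group and without either array of the 4-week group.

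For 4 weeks of norUDCA against untreated KO, again no named gene passed over all tested probes. Dio1 differed by -2.55 ± 0.29 log2 (SE, 5.86-fold lower), which passed over the named probes alone (0.018) and not over all probes (0.091). Within each list alone, 4 of the 10 list members passed, but Krt23, G6pc and Sult5a1 were the only tested members of theirs. The first value given for these 3 is therefore the unadjusted p, which was under 0.05 for 8.8% of all tested probes. Krt23 differed by -3.24 ± 0.55 (0.0010, and 0.18 adjusted over all probes), from 10.77 ± 0.34 (SD, n = 2) in KO to 7.53 ± 0.33 (SD, n = 2) after 4 weeks. Aldh3a2 differed by 1.10 ± 0.20 (0.0030 adjusted over its list of 2, and 0.22), G6pc by -1.16 ± 0.36 (0.018 and 0.45) and Sult5a1 by -1.84 ± 0.56 (0.017 and 0.44). Hsd3b4, a hydroxysteroid dehydrogenase with close paralogs, lies outside the naming rule in this comparison and is added here, as it passed against WT. It was detected on both KO arrays and on neither 4-week array, at least 116-fold lower after 4 weeks. Yet its KO arrays lay apart (14.28 and 11.23 log2), and it did not pass over all probes (0.20) or over the named probes (0.058). In all, 8 probes changed, 5 upward and 3 downward, of which the unnamed AK028310.1 was among the falls (-2.52 ± 0.20, adjusted p = 0.037). The count was 2 from the deposited assay-normalized intensities and 0 without any of the 6 KO arrays, treated or untreated, and rose to 13 and 16 without WT replicate 1 or 2.

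**Figure D3:**
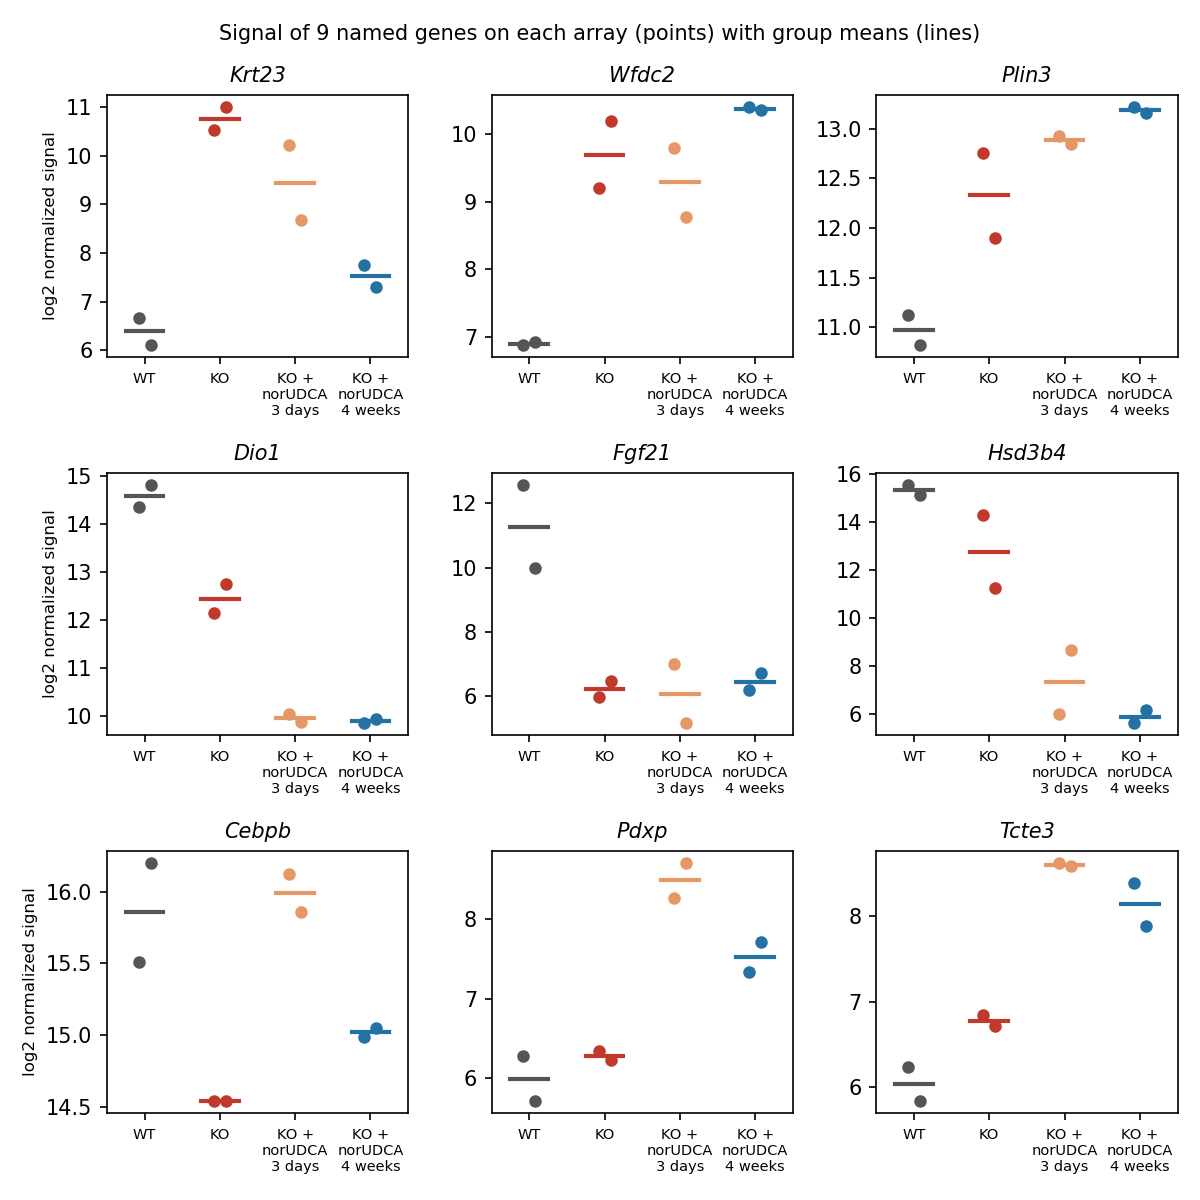
Each panel shows the normalized log2 signal of a named gene, with a point for each of the 8 arrays and a line for the mean of the 2 arrays of a group; vertical axes differ between panels and do not start at 0. Dio1 lay at 14.35 and 14.81 in WT and at 9.84 to 10.03 on the 4 norUDCA arrays, while Krt23 lay at 10.53 and 11.01 in untreated KO and at 7.76 and 7.29 after 4 weeks.

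The durations of treatment were also compared directly. By limma, 0 probes differed between 4 weeks and 3 days after adjustment, with 1499 at an unadjusted p under 0.05 and a smallest adjusted p of 0.25. Krt23 was 1.92 ± 0.55 log2 lower after 4 weeks than after 3 days without passing (adjusted p = 0.44), as was Cebpb with -0.97 ± 0.27 (0.44). Dio1 differed by -0.06 ± 0.29 (0.98). Across tested probes, the changes after 3 days and after 4 weeks correlated at r = 0.64, and at 0.50 in simulations without an effect, since both use the same KO arrays. Their covariance was 0.295, against 0.156 in the simulations, a difference of 0.139. The jackknife SE of 0.153 treats the 8 arrays as 1 sample without their groups, so it cannot decide whether this difference exceeds 0. The simulated noise had the same spread in all 4 groups, so the simulated 0.156 need not hold for the shared KO arrays. Of the 39 and 8 changed probes, 5 were shared with the same direction and 0 with opposite directions, against 0.01 for independent lists. Calls need both KO arrays, so part of this excess may come from the shared arrays. With 1 KO array used for each duration, so that no array was shared, the covariance was 0.155 and 0.156 in the 2 possible splits (r = 0.25 and 0.27), a check chosen after the data were seen.

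Whether treatment changes ran against the knockout changes was tested in the same way. The correlation of KO minus WT with 3 days minus KO was -0.25, and -0.29 for 4 weeks. Simulations without an effect gave -0.50 from the shared KO arrays. A correlation also shrinks as the changes themselves spread more widely, so the covariances were compared. The covariances were -0.160 and -0.157, close to the simulated -0.157 and -0.156. The simulated noise had the same spread in all 4 groups, whereas the WT replicates correlated less (0.935) than the KO replicates (0.963). Noise given to the shared KO arrays may therefore be too large. These values cannot decide whether there was opposition beyond that of the shared arrays. With the KO arrays split in the same way, the sign depended on the split: the covariance was 0.048 and -0.090 for 3 days, and 0.053 and -0.086 for 4 weeks. Among the 189 probes changed in KO minus WT, 10 also changed after 3 days in the opposite direction and 1 in the same direction, against 0.18 and 0.26 for independent lists. After 4 weeks 6 changed in the opposite direction and 0 in the same direction, against 0.04 and 0.05. Simulations with the knockout changes and no treatment effect gave at most 0 such probes after 3 days and 1 after 4 weeks, but they made almost no treatment calls. Noise in the shared KO arrays pushes probes called in both comparisons into opposite directions, so part of these overlaps may come from those arrays. Of the 189 probes, 134 (70.9%) had the opposite sign after 3 days and 141 (74.6%) after 4 weeks, whether or not the second change passed. The same simulations gave 63.5% on average for both durations, with highest values of 65.8% and 66.1%. They took the observed group means as the true ones, so noise already in KO minus WT counted as knockout effect. This may set the simulated share of opposite signs too low, so they cannot decide whether the observed shares exceed it.

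Treated knockouts were last set against WT. After 3 days 9 named genes passed over all tested probes, and after 4 weeks 8 passed. Dio1 fell by 4.63 ± 0.29 log2 (SE, 24.8-fold, adjusted p = 0.0063) after 3 days and by 4.70 ± 0.29 (25.9-fold, 0.0086) after 4 weeks. Hsd3b4 lay at 15.54 and 15.11 log2 in WT and at 6.01 and 8.67 after 3 days (0.027), when 1 of the 2 arrays detected it, and was at least 691-fold lower after 4 weeks (0.027). The lipid droplet protein Plin3 rose by 1.92 ± 0.31 (0.032) and 2.22 ± 0.31 (0.034). Wfdc2 rose at least 5.21-fold (0.041) and at least 11.1-fold (0.027), and Tcte3 at least 5.32-fold (0.014) and at least 3.85-fold (0.026). The transcript 4930433I11Rik was lower after both durations (0.021 and 0.023), with no fold given because only 1 of the 2 WT arrays detected it. Past the threshold after 3 days and not after 4 weeks were Krt23 (at least 8.26-fold higher, 0.038), Pdxp (at least 4.84-fold higher, 0.017) and Fgf21 (6.98 and 5.14 log2 against 12.58 and 9.98 in WT, 0.040, detected on 1 of the 2 treated arrays). Past it after 4 weeks and not after 3 days were Aldh3a2 (1.23 ± 0.20, 0.044) and Sult5a1 (-3.35 ± 0.56, 0.048). For these 5 genes the test between the durations did not pass. After 4 weeks Fgf21 lay at 6.17 and 6.7 log2, detected on 1 of the 2 arrays (0.067 against WT). Krt23 was then at least 2.18-fold higher than in WT (0.30). The calls of Krt23, Fgf21 and Wfdc2 after 3 days and of Aldh3a2 and Sult5a1 after 4 weeks were lost in 11 to 14 of 21 or 22 alternatives each.

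In counts of probes, 967 differed from WT after 3 days (599 higher, 368 lower) and 379 after 4 weeks (266 higher, 113 lower). With arrays scaled to the same median these became 1042 higher and 190 lower, and 847 higher and 135 lower, and with cyclic loess 397 and 327 after 3 days, and 128 and 86 after 4 weeks. Over probes detected on all 8 arrays, 875 were higher and 908 lower after 3 days, and 416 and 385 after 4 weeks. Without WT replicate 2 the counts were 1817 and 1298, without WT replicate 1 they were 435 and 252, and without either array of the treated group compared they fell to 3 and 0. The F test over all groups called 302 probes, 6 of them named: Dio1 (adjusted p = 0.015), Tcte3 (0.031), 4930433I11Rik (0.039), Pdxp (0.041), Hsd3b4 (0.047) and Krt23 (0.050).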

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

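The split of changed probes by mean signal was set out before its result was seen, and the other tests in this part were chosen after the results they bear on were seen.

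Signal of the positive control spots, which enters no comparison, was higher on the knockout arrays than on the wild type controls: the lowest of the 6 knockout arrays was 2.96 times the highest WT array. Median signals were 1691 and 2062 on the WT arrays and 6104 to 7913 on the others, over 129 spots per array. The 75th percentile of gene probe signal was lower on the WT arrays too (396.8 and 643.8, against 945.3 to 1511.9 on the others). Dimmer WT arrays as a whole would remove the gap once the spots are carried through the quantile normalization of the gene probes. The mean gap shrank from -1.85 to -0.64 log2, leaving WT replicate 1 (12.03) close to the lowest other array (12.08) and WT replicate 2 at 11.52, further below than the SD of the others (0.24), so overall dimness stays open as the cause. Weaker reverse transcription controls on both WT arrays are argued against by WT replicate 2, whose mean of 14.55 log2 lay above all 6 others (14.20 to 14.49), while WT replicate 1 was lowest at 13.98, and as it is not stated whether the positive control spots bind spiked or sample RNA, a tie to genotype or to how these arrays were run stays open and untested.

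More probes rose than fell in KO minus WT (136 and 53), mostly among dim probes. Over probes detected on all 8 arrays, 319 rose and 344 fell (48.1%, interval 44.3 to 52.0). That filter leaves out probes rising from undetected and also those falling to undetected. Of the changed probes with mean signal above the median of the tested probes, 52.7% rose (29 of 55, exact 95% interval 38.8 to 66.3), against 79.9% (107 of 134, 72.1 to 86.3) of those at or below it, the split that lower sensitivity of the WT arrays for dim probes would give. Against it, WT replicate 2 detected 41.4% of probes and KO replicate 2 detected 40.9%, and leaving out WT replicate 1 (33.3%) still gave 162 rises and 35 falls (82.2%, interval 76.2 to 87.3), so this explanation stays open. Rises outnumbered falls under each of 3 scalings, but the share moved with the scaling. It was 64.5% at the lowest (cyclic loess, interval 51.3 to 76.3) and 82.8% at the highest (same median). The intervals given here count probes of the same arrays as independent draws. They are therefore too narrow to decide whether the scaling between arrays is the whole cause. Genes that are off in WT liver and turned on in the knockout would give the same split, so a biological difference also stays open. The filter on dim probes asks more of probes detected only in WT. Without it, 6 probes rose and 3 fell in KO minus WT, too few to decide, so it stays open as a cause there. In the comparisons of treated knockouts with WT, rises still outnumbered falls without the filter (123 and 80 after 3 days, 27 and 13 after 4 weeks).

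The deposited assay-normalized intensities gave 3 changed probes after 3 days instead of 39. A candidate cause is the separate factor for the upper and lower rows of each array. With it, differences between these regions were 0.01 and 0.16 log2 on the KO arrays, -0.01 and 0.22 on the 3-day arrays, and -0.42 on WT replicate 1, which is not contrasted in this count. In the signal itself they were -0.04, -0.09, -0.08, -0.10 and 0.08. The 4-week arrays, which enter this count through the shared spread, went from -0.06 and 0.25 in the signal to -0.13 and 0.13. The factor thus did not widen the difference on every array. The signal divided by the unrounded factors also gave 3, which argues against rounding of the deposited values, and quantile normalization within each region, which removes any such factor, gave 44. No biological explanation applies to a count that differs between 2 versions of the same arrays.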

How the results depend on the processing

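No gene result changed direction: over 40 gene and comparison pairs and 856 values from alternatives, 645 kept their side of the threshold, 161 lost the call and 50 gained it. These pairs were taken because they had passed a threshold or, for list members, had an unadjusted p under 0.05 by limma. Some alternatives, such as the variance prior, leave the fold changes as they are. The stable direction was thus largely set by this choice and is weak evidence. For Krt23 in KO minus WT the adjusted p ran from 0.0027 to 0.19 (10 of 21 alternatives without a call), and for Dio1 from 0.0011 to 0.22 (13 of 22). Of the calls in 3 days minus WT, those of Krt23 and Wfdc2 were each lost in 13 of 21 alternatives, Fgf21 in 11 of 21, Hsd3b4 in 8 of 21, Plin3 in 9 of 22, 4930433I11Rik in 6 of 19, Pdxp and Tcte3 in 3 of 21 and Dio1 in 3 of 22. In 4 weeks minus WT, those of Sult5a1 were lost in 14 of 22, Aldh3a2 in 13 of 22, Tcte3 in 9 of 21, Plin3 in 8 of 22, Wfdc2 in 8 of 21, Hsd3b4 in 7 of 21, 4930433I11Rik in 7 of 19 and Dio1 in 3 of 22. The counts of changed probes moved most, and unless stated the cause was not tested. Counts below are in the order KO minus WT, 3 days minus KO, 4 weeks minus KO, 3 days minus WT, 4 weeks minus WT and F test, and give only those beyond 1.5 times the value reported (189, 39, 8, 967, 379 and 302).

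Arrays scaled to the same median gave 303, 90 and 43 in comparisons of the knockout, 982 for 4 weeks minus WT and 779 for the F test. This scaling moved the median difference of all tested probes to 0.48, 0.03 and 0.15 log2 in the 3 main comparisons, and to 0.50 and 0.61 in 3 days and 4 weeks minus WT. Cyclic loess gave 62 for KO minus WT, 214 for 4 weeks minus WT and 170 for the F test. Deposited assay-normalized intensities gave 3 for 3 days and 2 for 4 weeks minus KO, as did the unrounded row factors (3 and 2), an alternative chosen after seeing the data. No filter on dim probes gave 9, 0, 0, 203, 40 and 13 over more probes tested, and detection on all 8 arrays gave 663, 626, 59, 1783, 801 and 1346 over 9394 probes. An added constant of 39.4 gave 293, 88, 18 and, for the F test, 474. A variance prior with trend and robust fitting gave 975, 695, 139, 2217, 1251 and 1868, and array weights gave 33, 93, 20, 498, 237 and 111. With only the 2 groups compared, and 2 residual degrees of freedom, the counts were 0, 0, 3, 0 and 0. An adjusted p of 0.10 gave 805, 275, 29, 2394, 1129 and 1204. The named probes alone, a family of 163 chosen after seeing the data, gave 10, 6, 1, 9, 17 and 14. For 4 weeks minus 3 days, 11 came from the same median, 16 from detection on all 8 arrays and 69 from trend and robust fitting, and 0 from the other alternatives. Flagged spots kept, a 2-fold minimum and quantile normalization within the upper and lower rows left every count within 1.5 times.

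The replicate number as a block gave 7, 0, 0, 261, 68 and 0. Deviations of arrays with the same number correlated at -0.04 to 0.03 between groups, so no shared effect of the number was seen. This cannot show whether the numbers pair samples, which the labels do not state. The block takes a degree of freedom from the fit.

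Leaving out each array in turn gave 1 to 1084 for KO minus WT, 0 to 43 for 3 days minus KO, 0 to 16 for 4 weeks minus KO, 0 to 0 for 4 weeks minus 3 days, 3 to 1817 for 3 days minus WT, 0 to 1298 for 4 weeks minus WT and 0 to 838 for the F test. A group left with 1 array is assumed to vary like the others. KO minus WT fell to 1 without either KO array, to 55 and 54 without 3-day replicate 1 or 2, and to 17 without either 4-week array, although the treated arrays enter it only through the spread, the normalization and the filter on dim probes, and rose to 1084 without WT replicate 2. Both counts of treatment against KO were 0 without any of the 6 knockout arrays, and that of 4 weeks was 13 and 16 without WT replicate 1 or 2. The 3 days minus WT count was 435 and 1817 without WT replicate 1 or 2, 3 without either 3-day array, and 198 and 195 without 4-week replicate 1 or 2. The 4 weeks minus WT count was 252 and 1298 without WT replicate 1 or 2, 86 and 61 without 3-day replicate 1 or 2, and 0 without either 4-week array. The F test gave 68 and 838 without WT replicate 1 or 2, 8 and 0 without KO replicate 1 or 2, 1 and 0 without 3-day replicate 1 or 2, and 0 without either 4-week array.

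Under the alternatives run, the covariance beyond the simulated value moved from the value reported by less than its jackknife SE. With each array left out in turn it ran, for opposition, from -0.067 to 0.053 (3 days, SE 0.094) and from -0.059 to 0.058 (4 weeks, SE 0.087), and for similarity from 0.013 to 0.208 (SE 0.153, from 0.139 reported), and the similarity reported was itself less than its SE from 0. The variance prior and the fit of only 2 groups were not run for these covariances, whose fold changes they leave as they are. No alternative was run for the gene list tests, with the estimated correlation and fry among them. Signal over background leaves only a nominal bound on the fold for probes that a group did not detect, which held for 91 of the 136 rises and 14 of the 53 falls in KO minus WT.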

Other observations

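Hba-a1, an alpha globin gene with a near-identical copy and the only tested member of the blood list, differed within WT: its log2 signal was 19.04 and 16.17 on the 2 WT arrays, 15.93 and 15.63 in untreated KO, 13.63 and 14.24 after 3 days, and 15.43 and 15.43 after 4 weeks. The male-biased urinary protein gene Mup1, of a family of close paralogs, lay between 19.79 and 20.68 on all 8 arrays. Gpbar1, the membrane receptor for bile acids, was detected on 1 of 2 arrays in WT, in none in untreated KO and on 1 of 2 in each treated group, with no difference past the threshold in the main comparisons.

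Probes that share a gene identifier were compared after the data were seen. Over 969 identifiers with several tested probes, their log2 differences correlated across identifiers, which are not independent replicates, at 0.38 for KO minus WT, 0.44 for 3 days minus KO and 0.37 for 4 weeks minus KO. Of the changed probes with such a partner, 16 of 19 in KO minus WT and 8 of 10 in 3 days minus KO had a partner with the same sign.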
